A study of Mus musculus with 7 samples.

How the data were processed

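Whole liver RNA was measured on 7 Affymetrix whole-transcript (Gene ST type) arrays, 1 array per mouse liver sample. The mice were males of mixed strain (129S4 and C57BL/6) with both Dicer1 alleles flanked by loxP sites. They received AAV8-Ttr-Cre, an adeno-associated virus of serotype 8 that carries the Cre recombinase under a transthyretin promoter, which is active in hepatocytes. Per the labels, livers were taken after a 4 hour fast at 0, 2 or 4 weeks, flash frozen, and extracted with Trizol. The RNA was labelled with biotin by the Affymetrix whole-transcript sense target assay, per the labels' protocols. Groups came from the sample labels: 3 control arrays (0 weeks), 2 arrays at 2 weeks after the virus and 2 arrays at 4 weeks. The labels call the arrays of a group biological replicates.

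The deposited values are log2 signals, 1 per probe set (transcript cluster) and array. The scale was read from the values, which ran from 3.15 to 14.7. GCOS version 1.4 is named in the submitters' processing notes, without a role. The summarisation, background and normalization methods are not given in the sources used here. The array medians were nearly equal, so the authors had brought the arrays to a common level in some way. No filter, detection call or scan date was given with the values, so no detection limit or batch could be used. For arrays, the number of arrays per group (3, 2 and 2) limits the precision.

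The table held 21093 probe sets, of which 17709 had 1 gene symbol in the platform annotation, 187 had several and 3197 were unnamed. By gene number, 17648 of the named probe sets matched a table of RefSeq genes (assembly GRCm38.p6), which changed 0 symbols. It was used for names only, and no genome positions are given. Of the 16819 distinct genes, 463 had more than 1 probe set, and the one with the highest mean over all arrays was kept. In 0 of these genes did probe sets move by over 0.5 log2 units in opposite directions after Cre. Probe sets without a single gene name were left out of the tests of named genes.

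The log2 values were used as deposited by the authors, with no further scaling and no filter on dim genes. A linear model with the 3 groups was fitted to each gene with limma (version 3.58.1, R 4.3.3; lmFit and eBayes). Contrasts were 2 weeks against control, 4 weeks against control, 4 weeks against 2 weeks, and the mean of both times against control (called after Cre). The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 16819 genes. An adjusted p under 0.05 counted as changed. The fit had 4 residual degrees of freedom and 1.69 prior degrees of freedom. All log2 fold changes are given with the standard error (SE) of the fit.

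Gene lists for 36 pathways, cell types and reported microRNA targets were fixed before the data were examined, as were the tests, the rule for named genes and all but 5 of the alternative settings. Of 950 list entries, 825 were measured. A list was tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists of a comparison). It was tested again with the correlation estimated for each list, and with fry, which asks whether members move, on balance, one way. With an estimated correlation, 0 of the lists called by camera passed in any of the comparisons. In that setting camera also uses only the 4 residual degrees of freedom of the fit, which by itself raises p-values. The estimated correlations of the clock (-0.008) and p53 (0.007) lists lay below the preset 0.01. Their unadjusted camera p at 2 weeks still rose, from 0.000153 to 0.0151 and from 1.57e-06 to 0.00796. The lost calls therefore do not come from correlated members alone. Counts of changed members are given after adjustment over all genes and after adjustment over the list alone.

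The genes named were Dicer1 and Lpl, and in each comparison the 10 with the largest log2 rise and the 10 with the largest log2 fall. These had to pass the threshold, with no overlap between the arrays of the 2 groups, and clone-like or predicted names were left out. In each list, up to 4 passing members with the smallest adjusted p and up to 2 non-passing members with the highest mean level were named. Members of the Mup, Cyp2, Cyp3a, Saa and other near-identical families may share probes, so their values are uncertain as to the member.

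The same steps were tested on simulated data drawn from the means and spreads of the 16819 real genes, with 200 genes changed in each of 10 draws. Of changes of 0.5, 1 and 2 log2 units, 59.5%, 94% and 99.1% were found at 2 weeks and 59.7%, 94.1% and 99.1% at 4 weeks. For the contrast after Cre these shares were 72.7%, 96.8% and 99.4%. Of the genes called, 4.4% to 5.1% were unchanged ones. Camera called 10 of 10 simulated lists shifted by 0.3 and 0 of 10 unshifted lists. These simulated genes were independent, which the genes of a real list are not. They were also normally distributed, with the same change on all arrays after Cre, so a share of false calls near the threshold was built in. The real arrays had exact ties and unequal responses, so these shares need not hold for them.

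Exact ties between arrays were frequent: 9824 genes (58.4%) had at least 2 arrays at exactly the same value, and 6422 had at least 3. Of the genes called after Cre, 3% had such a tie. A fit without tied genes was added after the data were seen. The other 4 alternatives added at that stage leave Lpl, the matrix and stellate genes, Dicer1 or Ccng1 out of a list. The settings chosen beforehand were median centring, quantile normalization, filters at the 40th and 60th percentile of mean level, the mean of all probe sets of a gene, and all probe sets of the table. An intensity trend, a robust prior, fits of 2 groups, a replicate block, other thresholds and leaving out each array were chosen then too. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and tables were joined with pandas 2.3.3.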

Results

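Gene expression was profiled in whole liver of male mice whose floxed Dicer1 gene was to be deleted in hepatocytes by AAV8-Ttr-Cre. Dicer1 encodes the ribonuclease that cuts microRNA precursors to their mature form. The title of the series names the repression of lipoprotein lipase (Lpl) by miR-29a, and the design asks how the liver transcriptome changes when hepatocytes lose Dicer1. There were 3 control arrays at 0 weeks, 2 arrays at 2 weeks and 2 arrays at 4 weeks after the virus. No group received a virus without Cre, and no control was taken at 2 or 4 weeks. Differences from control may therefore come from the virus, Cre itself or the elapsed weeks as well as from the loss of Dicer1. The median log2 signals of the 7 arrays were nearly equal, and 16819 genes were compared. The first principal component held 62% of the variance and placed the 3 controls between -23.8 and -22.4. The arrays after Cre lay at 6.57 and 24.3 (2 weeks, replicates 1 and 2) and at 18.4 and 19.8 (4 weeks), so 2 week replicate 1 lay closest to the controls.

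The deleted gene was lower on each of the 4 arrays after Cre. Dicer1 read 8.73, 8.71 and 8.58 on the control arrays, 8.03 and 7.79 at 2 weeks, and 7.97 and 8.05 at 4 weeks. It fell by 0.76 on the log2 scale at 2 weeks (SE 0.09, adjusted p = 0.0158, limma, n = 3 and 2) and by 0.66 at 4 weeks (SE 0.09, adjusted p = 0.0159). Which exons the Dicer1 probes cover is not given in the sources used here, so the signal checks the labels only as far as the probes reach the deleted part. Whole liver also holds cells that the virus does not delete in.

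Lpl, which hydrolyses the triglycerides of circulating lipoproteins, rose 6.68-fold at 2 weeks and 5.56-fold at 4 weeks. Its control arrays read 7.10, 7.36 and 7.18, against 9.11 and 10.80 at 2 weeks and 9.54 and 9.84 at 4 weeks. The log2 fold changes were 2.74 (SE 0.47, adjusted p = 0.0358, limma, n = 3 and 2) and 2.47 (SE 0.47, adjusted p = 0.0338). Leaving out Cre 2 wk replicate 1 or 2 gave 3.58 or 1.90 at 2 weeks. The difference between the times was -0.26 (SE 0.52, adjusted p = 0.941). In fits of 2 groups only, Lpl at 2 weeks had an adjusted p of 0.0937 and Dicer1 one of 0.0511. Without control replicate 1, 2 or 3, the adjusted p of Lpl at 2 weeks was 0.111, 0.114 and 0.129, and at 4 weeks 0.104, 0.106 and 0.116. Without Cre 4 wk replicate 1 or 2 it was 0.137 and 0.17 at 4 weeks, and that of Dicer1 0.091 and 0.0806. Dicer1 also missed the threshold without control replicate 1, 2 or 3, with adjusted p-values of 0.0622, 0.0731 and 0.0621 at 2 weeks and 0.0589, 0.0673 and 0.0521 at 4 weeks.

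**Figure D1:**
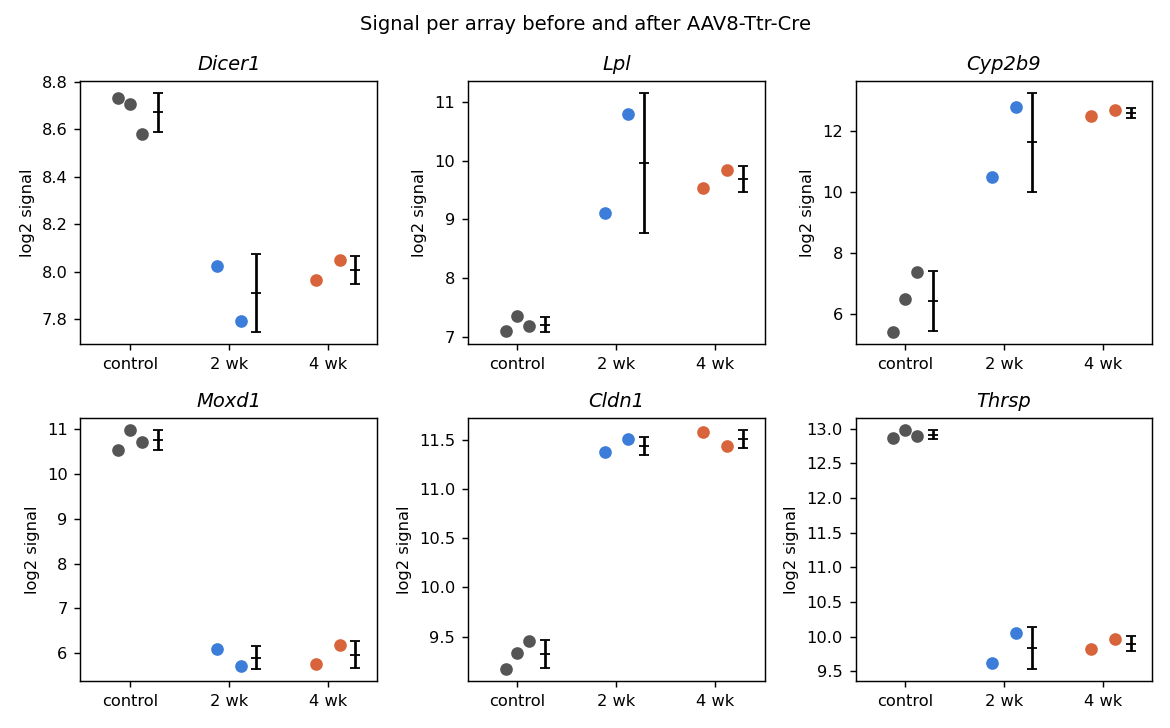
Log2 signal (y axis) of 6 genes in the control, 2 week and 4 week groups (x axis), with 1 point per array and the mean ± SD of each group beside the points. Lpl read 7.10 to 7.36 on the control arrays and 9.11 to 10.80 after Cre, while Dicer1 read 8.58 to 8.73 and 7.79 to 8.05.

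At 2 weeks after the virus, 582 genes were higher and 415 lower than in the control livers, 96 and 52 of them by at least 2-fold. The largest rise was that of Cyp2b9, a cytochrome P450 that is normally more abundant in female liver, at 37.2-fold (log2 5.22, SE 0.83, adjusted p = 0.0298, limma, n = 3 and 2). Its 2 week arrays read 10.49 and 12.79 against a control mean of 6.42, so leaving out either moves this fold change by over 2 times. Loxl4, a lysyl oxidase that cross-links collagen, rose 6.54-fold, the tubulin gene Tubb2a 5.77-fold, and Spon2, a secreted matrix protein, 4.66-fold. Chka, the first enzyme of phosphatidylcholine synthesis from choline, rose 4.42-fold, the tight junction gene Cldn1 4.34-fold, and the transcription factor Jun 4.32-fold. Ndrg1 (4.19-fold) and the phosphatase Phospho1 (4.16-fold) completed the 10 largest rises with Lpl.

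The largest fall at 2 weeks was that of Moxd1, a male-biased liver gene, which was 29.0-fold lower (log2 -4.86, SE 0.20, adjusted p = 0.00223). Thrsp, which promotes fatty acid synthesis, was 8.46-fold lower, and Nnmt, the nicotinamide methyltransferase, 7.61-fold lower. Wee1, a kinase that restrains entry into mitosis, fell by 2.89 on the log2 scale (SE 0.05, adjusted p = 8.51e-05). The growth factor gene Nrg4 was 5.53-fold lower, Nmrk1, a kinase of NAD synthesis, 4.38-fold lower, and Pfkfb3, a regulator of glycolysis, 4.37-fold lower. The falls also included 3 members of the circadian clock list, namely Ciart (7.26-fold), Dbp (5.32-fold) and Usp2 (4.69-fold).

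Among lists of reported microRNA targets, those of miR-122 and miR-29 were higher at 2 weeks. Of 29 measured targets of miR-122, the most abundant liver microRNA, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a mean log2 fold change of 0.35 (camera adjusted p = 0.00121; adjusted p = 0.731 with an estimated correlation). Cyclin G1 (Ccng1) rose 2.82-fold, the microtubule-binding gene Mapre1 1.69-fold, the receptor gene Tgfbr1 1.56-fold and citrate synthase (Cs) 1.53-fold. The aldolase gene Aldoa was at 0.92 (SE 0.27, adjusted p = 0.116) and Rhoa at 0.07. Without Cre 2 wk replicate 2, the miR-122 list had an adjusted p of 0.15.

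Of 26 reported miR-29 targets, 4 rose and 0 fell (10 and 0 adjusted over the list alone), with a mean of 0.35 (camera adjusted p = 3.67e-05; adjusted p = 0.396 with an estimated correlation). Besides Lpl, which the series title names as a target, these were the DNA methyltransferases Dnmt3b (1.82-fold) and Dnmt3a (1.55-fold) and the collagen gene Col15a1 (1.29-fold). Igf1 was at 0.05 and Mcl1 at -0.04, both short of the threshold. Without Lpl, the list's mean was 0.26 (adjusted p = 0.000122; adjusted p = 0.527 with an estimated correlation). The let-7 target list was not called: of 24, 1 rose and 1 fell (3 and 2 adjusted over the list alone), Plagl2 and Dicer1 itself, and the camera adjusted p was 0.964. Dicer1 is the deleted gene, and the let-7 list was not tested without it. The test of the let-7 list pointed down and its median was -0.01, while its mean was 0.12.

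Of 13 transcripts in the microRNA pathway list, 2 rose and 1 fell, and the list was called higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.731 with an estimated correlation). Tnrc6a (2.23-fold) and Tnrc6b (1.90-fold), which encode the silencing partners of Argonaute proteins, rose, and Dicer1 fell. Ago2, the main slicing Argonaute, was at 0.01 and Ago1 at 0.00. Without control replicate 3 and without Cre 2 wk replicate 2, the list's adjusted p was 0.0671 and 0.0519. The p53 target list was higher too, with 6 of 19 members rising and 0 falling (10 and 0 adjusted over the list alone; camera adjusted p = 3.67e-05, adjusted p = 0.272 with an estimated correlation). The antiproliferative gene Btg2 rose 3.60-fold, Ccng1 2.82-fold, the death receptor gene Eda2r 2.44-fold and the translesion polymerase Polk 1.65-fold, while Fas was at 1.07 (SE 0.27, adjusted p = 0.0778).

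Genes of fatty acid and triglyceride synthesis were lower at 2 weeks, 3 of 21 having fallen and 1 risen (7 and 2 adjusted over the list alone; camera adjusted p = 0.00379, adjusted p = 0.558 with an estimated correlation). Thrsp, the fatty acid elongase Elovl6 (2.00-fold lower) and the triglyceride synthase Dgat2 (1.31-fold lower) fell, and the carbohydrate-responsive transcription factor gene Mlxipl rose 1.52-fold. Scd1 was at -0.36 (SE 0.15, adjusted p = 0.24) and Fads2 at 0.00. Without Cre 2 wk replicate 1, the adjusted p was 0.078. In the same arrays the circadian clock list was lower, with 7 of 17 members falling and 2 rising (9 and 3 adjusted over the list alone; mean -0.71, camera adjusted p = 0.00121, adjusted p = 0.272 with an estimated correlation). Per3 was 2.59-fold lower and Nr1d2, a clock repressor, 2.90-fold lower, whereas Bhlhe40 was at -0.95 (SE 0.36, adjusted p = 0.193). The list did not fall as a whole. Its 4 genes that peak around dawn (Arntl, Clock, Cry1 and Nfil3) had a mean of 1.015 and the 13 others -1.241. This grouping was made after the values were seen.

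Male-biased liver genes were lower at 2 weeks as a list (mean -0.83, camera adjusted p = 0.00102, adjusted p = 0.731 with an estimated correlation), although Moxd1 was the 1 of 18 members that passed on its own (0 rose and 3 fell adjusted over the list alone). The major urinary protein gene Mup3 was at -0.52 and the complement gene C8b at -0.02. The mean of this list was -0.32 on 2 week replicate 1 and -1.35 on replicate 2, and without replicate 2 the adjusted p was 0.177. Of the matrix and fibrosis list, 2 of 24 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0031, adjusted p = 0.731 with an estimated correlation), the 2 being the laminin gene Lamb1 (1.30-fold) and Tgfbi (1.28-fold). Of the bile duct and progenitor markers, 0 of 16 changed on their own (0 adjusted over the list alone). As a list they were higher by a mean of 0.23 (camera adjusted p = 0.0327, adjusted p = 0.731 with an estimated correlation), with Sox9 at 0.31 and Onecut1 at 0.64. Without Cre 2 wk replicate 2, the matrix list had an adjusted p of 0.15 and the bile duct list one of 0.651, and the latter had 0.0581 without control replicate 2.

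By fry, which asks whether members move one way on balance, the lists passing at 2 weeks were those of the clock (adjusted p = 0.00145), p53 targets (0.00288), lipid synthesis (0.0167), miR-29 targets and the microRNA pathway (both 0.0282). The miR-122 (0.169), male-biased (0.109), matrix (0.201) and bile duct (0.223) lists did not pass by fry.

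The counts at 2 weeks changed when an array was left out, which also lowers the residual degrees of freedom below 4. Part of the change can thus come from lost power and not from the values of that array. Of the 997 genes called, 0 changed sign without any of the arrays. They were 1091 higher and 1077 lower without Cre 2 wk replicate 1, 181 and 148 without replicate 2, 120 and 70, 83 and 44, and 24 and 17 without control replicate 1, 2 or 3, and 171 and 105 in a fit of these groups alone.

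At 4 weeks after the virus, 866 genes were higher and 777 lower than in the controls, 124 and 98 of them by at least 2-fold. Cyp2b9 rose 72.8-fold (log2 6.19, SE 0.83, adjusted p = 0.0163, limma, n = 3 and 2). Rian, an imprinted noncoding RNA, rose 9.32-fold, gelsolin (Gsn), which severs actin filaments, 7.33-fold, and Ndrg1 6.65-fold. Loxl4 (6.10-fold), Jun (5.28-fold), Tubb2a (5.13-fold), Spon2 (4.78-fold) and Cldn1 (4.55-fold) were again among the 10 largest rises, with Lpl.

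The largest fall at 4 weeks was that of Slc10a2, a sodium-dependent bile acid transporter, which was 30.2-fold lower (log2 -4.92, SE 0.41, adjusted p = 0.00772), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 6.95-fold lower (log2 -2.80, SE 0.55, adjusted p = 0.0374). The arrays at 4 weeks differed widely for Cyp7a1, at 8.79 and 10.75 against a control mean of 12.57, and leaving out either moves its fold change by close to 2 times. Moxd1 was 27.9-fold lower, the acute phase gene Saa2 9.84-fold lower, and Lpin1, a phosphatidate phosphatase of triglyceride synthesis, 9.57-fold lower. Thrsp (8.09-fold), Wee1 (6.82-fold), the sodium-calcium exchanger gene Slc8a1 (6.43-fold), Ciart (6.25-fold) and the metallothionein gene Mt1 (6.06-fold) completed the list of largest falls.

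The miR-122 targets stayed higher at 4 weeks, where 7 of 29 rose and 0 fell (13 and 0 adjusted over the list alone; mean 0.40, camera adjusted p = 0.000557, adjusted p = 0.793 with an estimated correlation). Rell1 rose 2.28-fold, Mapre1 1.92-fold, Tgfbr1 1.74-fold and Cs 1.68-fold. Of the miR-29 targets, 3 of 26 rose and 0 fell (5 and 0 adjusted over the list alone; mean 0.28, camera adjusted p = 0.0104, adjusted p = 0.693 with an estimated correlation), namely Lpl, Dnmt3b (1.69-fold) and Dnmt3a (1.64-fold). Without Cre 4 wk replicate 2 the miR-29 list had an adjusted p of 0.174. The let-7 targets were again not called as a list (camera adjusted p = 0.945), with 4 of 24 higher and 2 lower (4 and 2 adjusted over the list alone). Among them cyclin D1 (Ccnd1) rose 3.80-fold, Plagl2 1.57-fold and Lin28a, which blocks let-7 maturation, 1.19-fold.

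In the microRNA pathway, Tnrc6a (2.21-fold), Tnrc6b (1.66-fold) and Tnrc6c (1.48-fold) rose and Dicer1 fell among 13 members (4 higher and 1 lower adjusted over the list alone). The list's camera adjusted p was 0.101 at this time. Of 19 p53 targets, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.228), with Btg2 at 2.49-fold, Trp53inp1 at 2.17-fold and Ccng1 at 1.83-fold. Matrix and fibrosis genes were higher as a list, with 3 of 24 rising and 0 falling (5 and 0 adjusted over the list alone; camera adjusted p = 0.0297, adjusted p = 0.823 with an estimated correlation). The matrix proteases Mmp14 (2.47-fold) and Mmp12 (1.32-fold) and Tgfbi (1.24-fold) rose, while Fn1 was at 0.16 and the collagen gene Col1a2 at 0.07. Without control replicate 3 and without Cre 4 wk replicate 2, the matrix list had adjusted p-values of 0.198 and 0.183.

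Fatty acid and triglyceride synthesis was lower at 4 weeks, with 6 of 21 members falling and 1 rising (7 and 1 adjusted over the list alone; mean -0.48, camera adjusted p = 0.00548, adjusted p = 0.693 with an estimated correlation). Thrsp, Lpin1, Elovl6 (2.12-fold lower) and the acetyl-CoA carboxylase gene Acacb (1.88-fold lower) fell, and Scd1 was at -0.34 (SE 0.15, adjusted p = 0.244). The clock list was lower in the same arrays, with 7 of 17 falling and 3 rising (7 and 3 adjusted over the list alone; camera adjusted p = 0.0385, adjusted p = 0.693 with an estimated correlation). Usp2 (4.76-fold lower), Dbp (3.19-fold lower) and Per3 (2.17-fold lower) fell and the clock repressor Nr1d1 rose 3.83-fold. The 4 genes that peak around dawn had a mean of 0.69 and the 13 others -0.81. Without control replicate 2, control replicate 3 or Cre 4 wk replicate 2, the clock list had adjusted p-values of 0.0569, 0.0643 and 0.166.

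Lists of other lipid and bile acid genes held members that went both ways at 4 weeks and were not shifted, while the clock list was lower in the same arrays. For triglyceride uptake and lipases, 2 of 22 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.35), including the lipoprotein receptor Lrp1 (1.26-fold higher), the lipase maturation factor Lmf1 (1.45-fold lower) and the monoglyceride lipase Mgll (1.99-fold lower). Its test pointed down and its median was -0.06, while its mean was 0.03. Of the lipid droplet proteins, 1 of 18 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.228): perilipin 2 (Plin2) rose 1.73-fold, and seipin (Bscl2) was 1.55-fold lower. Of the lipoprotein assembly and reverse transport genes, 4 of 19 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.414), with the secretion gene Tm6sf2 at 2.30-fold, the cholesterol efflux gene Abca1 at 1.60-fold and Mttp, which loads lipid onto apolipoprotein B, at 1.38-fold. Of the bile acid genes, 3 of 18 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.924). Nr0b2, the repressor of Cyp7a1, rose 3.55-fold, the bile salt export pump Abcb11 1.88-fold and Akr1d1 1.44-fold, and the test pointed up while the mean was -0.06 and the median -0.03. Of the glucose metabolism genes, 2 of 18 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.377), with liver pyruvate kinase (Pklr) 2.55-fold lower, glycogen synthase 2 (Gys2) 1.73-fold lower and the insulin receptor substrate Irs2 1.62-fold higher.

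The 2 lists of sex-biased genes were called in opposite directions by camera at 4 weeks, with few members passing on their own. The male-biased list was lower, with 4 of 18 falling and 0 rising (6 and 2 adjusted over the list alone; mean -0.84, camera adjusted p = 0.00941, adjusted p = 0.793 with an estimated correlation). Besides Moxd1, the complement regulator Susd4 was 3.57-fold lower, complement component C6 3.24-fold lower and Keg1 2.24-fold lower. The female-biased list was higher, with 2 of 14 rising and 0 falling (5 and 0 adjusted over the list alone; mean 1.57, camera adjusted p = 0.0297, adjusted p = 0.811 with an estimated correlation). Cyp2b9 and Cyp3a44 (1.39-fold) rose, Cyp2c39 was at 2.30 (SE 1.20, adjusted p = 0.32) and Cyp17a1 at -1.32 (SE 0.65, adjusted p = 0.287). Members of these P450 families may share probes, and without Cre 4 wk replicate 1 the female-biased list had an adjusted p of 0.0749.

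By fry, the lipid synthesis, clock and acute phase lists (each adjusted p = 0.0131) and the microRNA pathway and microRNA gene lists (each 0.0477) passed at 4 weeks. The miR-29 (0.0603), miR-122 (0.102), male-biased (0.103), female-biased (0.187) and matrix (0.23) lists did not.

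The counts at 4 weeks also changed when an array was left out, with the same loss of degrees of freedom. Of the 1643 genes called, 0 changed sign without any of the arrays. They were 37 higher and 26 lower without Cre 4 wk replicate 1, 56 and 38 without replicate 2, and 266 and 191, 194 and 118, and 183 and 111 without control replicate 1, 2 or 3.

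**Figure D2:**
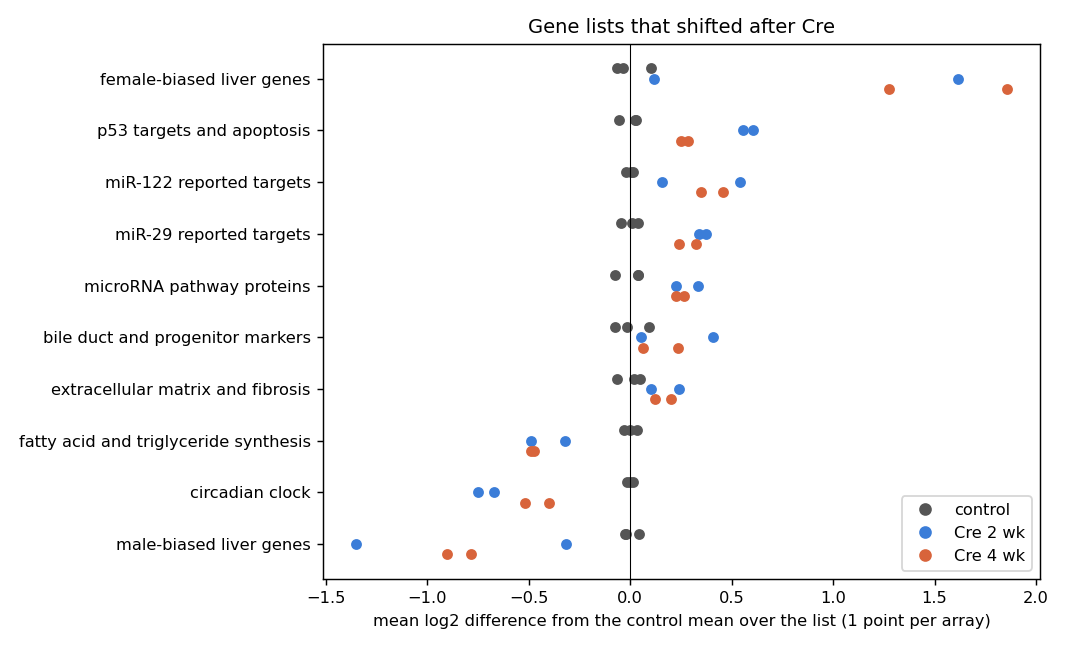
Mean log2 difference from the control mean over the genes of a list (x axis) for the 10 lists called in at least 1 comparison with control (y axis), with 1 point per array and colours for the control, 2 week and 4 week groups. The circadian clock list lies between -0.75 and -0.40 on the 4 arrays after Cre, and 2 week replicate 1 lies nearest to the controls for the male-biased list at -0.32.

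Averaged over both times, 1142 genes were higher and 1029 lower after Cre than in the controls, and the genes named above led both directions, from Cyp2b9 (52.1-fold higher, SE 0.69 on the log2 scale, adjusted p = 0.00925, n = 3 and 4) to Moxd1 (28.4-fold lower, SE 0.16, adjusted p = 0.000676). Saa2 was 5.57-fold lower (adjusted p = 0.0478) and Rian 6.46-fold higher (adjusted p = 0.0339). The same 9 lists as at 2 weeks were called, except that the female-biased list (2 of 14 rose, 2 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.725 with an estimated correlation) stood in place of the bile duct markers (camera adjusted p = 0.0614). The adjusted p was 0.443 with an estimated correlation for the miR-29, p53, lipid synthesis and clock lists. It was 0.692 with an estimated correlation for the microRNA pathway and male-biased lists, and 0.725 for the miR-122 and matrix lists. By fry, the male-biased (adjusted p = 0.0541), miR-122 (0.0664), matrix (0.114) and female-biased (0.154) lists did not pass after Cre, while the other 5 did, the highest at 0.0187. Without control replicate 1, 2 or 3 the counts were 496 and 358, 351 and 219, and 333 and 240, and without Cre 4 wk replicate 1 or 2 they were 510 and 371, and 524 and 389.

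Other metabolic and stress lists were not called by camera after Cre, and of these the acute phase list passed by fry. Of the fatty acid oxidation and ketogenesis genes, 1 of 21 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.293), the pyruvate dehydrogenase kinase Pdk4, which rose 2.75-fold at 2 weeks. Of the cholesterol synthesis genes, 0 of 18 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.196), the isomerase Ebp, which was 1.53-fold lower at 4 weeks. Drug metabolism genes included 3 of 21 that rose and 2 that fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.8), such as the oxidase Aox3 (1.44-fold higher at 4 weeks) and Fmo5 (1.47-fold lower at 4 weeks). Of the secreted plasma proteins, 4 of 20 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.8), with the fibrinogen chains Fga (3.01-fold) and Fgg (1.31-fold) higher and complement C9 2.99-fold lower at 4 weeks, and albumin (Alb) at 0.02. The acute phase list had 2 of 20 higher and 4 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.295, fry adjusted p = 0.0349, lower), with the lipopolysaccharide-binding protein Lbp 2.49-fold higher and the receptor Il6ra 2.60-fold lower at 4 weeks. In the ER stress list, 1 of 21 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.549), with Herpud1 2.74-fold lower at 2 weeks and Hspa5 at -0.37 then. Of 16 oxidative stress genes, 2 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.377), the glutathione synthesis genes Gclc (1.93-fold) and Gclm (1.33-fold), and catalase (Cat) was at 0.07.

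Lists of growth, immunity and other cell types had no or few members called after Cre, where 12.9% of all named genes were called. Fry's mixed test asks whether members move in either direction. It passed for the cell cycle (adjusted p = 0.0111), interferon (0.0111), antigen presentation (0.0305), ribosomal (0.000153), stellate cell (0.00733) and microRNA gene (0.00293) lists. The fetal, erythroid, Kupffer cell, T and NK cell, B cell and neutrophil lists did not pass it (0.0536 or higher). Of 30 cell cycle genes, 0 changed by limma (0 adjusted over the list alone; camera adjusted p = 0.293), with Mcm7 at 0.22 at 4 weeks. Of 19 fetal and imprinted genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.162), the imprinted gene Peg3 (2.44-fold), and Meg3, a noncoding RNA, was at 2.82 at 4 weeks (SE 0.91, adjusted p = 0.122). Interferon-stimulated genes had 2 of 21 higher and 0 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.313), and at 4 weeks Irf1 was 1.70-fold higher and Bst2 1.38-fold lower. Of the antigen presentation and inflammation genes, 0 of 20 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.8), the NF-kB inhibitor Nfkbia, 1.46-fold lower at 4 weeks. Of 9 ribosomal protein genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.196), Rpl8, 1.38-fold lower at 4 weeks.

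Stellate cell and myofibroblast markers had 2 of 20 higher and 0 lower (2 and 0 adjusted over the list alone; mean 0.12, camera adjusted p = 0.168), namely the growth factor gene Hgf (1.34-fold) and the receptor gene Pdgfrb (1.24-fold), with decorin (Dcn) at 0.28 at 2 weeks (SE 0.11, adjusted p = 0.209). Kupffer cell and macrophage markers (0 of 23 changed, camera adjusted p = 0.726), T and NK cell markers (0 of 14, 0.872), B and plasma cell markers (0 of 12, 0.886) and neutrophil markers (0 of 10, 0.886) had no member that changed in the limma fit, nor adjusted over the list alone. The Kupffer marker Clec4f was at 0.04 and the T cell chemokine Ccl5 at -0.01 at 4 weeks. Of 6 erythroid markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.293), the carbonic anhydrase Car1 (1.79-fold lower). Of the 171 microRNA genes with a probe set, which measures mostly the precursor region and not the mature microRNA, 4 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.313). At 2 weeks Mir107 rose 1.71-fold and Mir103-2 1.47-fold, and at 4 weeks Mir431 rose 1.37-fold and Mir24-2 1.21-fold. Median and mean differed in sign after Cre for the bile acid (0.02 and -0.08), secreted protein (-0.004 and 0.007), Kupffer cell (-0.01 and 0.03), sinusoidal endothelial (0.01 and -0.02) and neutrophil (-0.01 and 0.02) lists. They also differed in sign for the drug metabolism and neutrophil lists at both times and for the bile acid, secreted protein and acute phase lists at 2 weeks. The let-7 list at 4 weeks had a median of -0.005 and a mean of 0.13. At 4 weeks the test pointed against the mean for the secreted protein, T cell and neutrophil lists, besides the lists named above.

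Between 2 and 4 weeks, Nr1d1 was the 1 gene that changed by limma, and it was 6.26-fold higher at 4 weeks (log2 2.65, SE 0.12, adjusted p = 0.0155, n = 2 and 2). Against control it had fallen by 0.71 at 2 weeks (SE 0.11, adjusted p = 0.027) and had risen at 4 weeks. No gene was lower at 4 than at 2 weeks, and 1250 genes had an unadjusted p under 0.05 in either direction. The p53 targets were lower at 4 than at 2 weeks as a list (mean -0.32, camera adjusted p = 9.71e-07, adjusted p = 0.17 with an estimated correlation), with 0 of 19 members passing on their own (0 higher and 4 lower adjusted over the list alone) and Trp53inp1 at -0.29 (SE 0.23). The acute phase genes were lower as well (mean -0.43, camera adjusted p = 0.00211, adjusted p = 0.269 with an estimated correlation), with 0 of 20 passing (0 higher and 1 lower adjusted over the list alone) and haptoglobin (Hp) at -0.13. Without Cre 4 wk replicate 1 the acute phase list had an adjusted p of 0.0587.

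The sinusoidal endothelial markers were higher at 4 than at 2 weeks as a list (mean 0.21, camera adjusted p = 0.00199, adjusted p = 0.997 with an estimated correlation), with 0 of 17 passing (1 and 0 adjusted over the list alone) and the lectin gene Clec4g at 0.72 (SE 0.14, adjusted p = 0.381). After Cre against control, 0 of these 17 changed (0 adjusted over the list alone; camera adjusted p = 0.8). Their mean was -0.32 on 2 week replicate 1, and without that array the difference between the times was 0.01 (adjusted p = 0.875). The call of Nr1d1 was lost in a fit of these 2 groups alone and when any of the 7 arrays was left out. The control arrays do not enter its difference of 2.65, so leaving 1 out changes only the spread and degrees of freedom. By fry, the p53 and acute phase lists (adjusted p = 0.0365) and the clock list also moved between the times, the last with adjusted p = 0.0241.

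**Figure D3:**
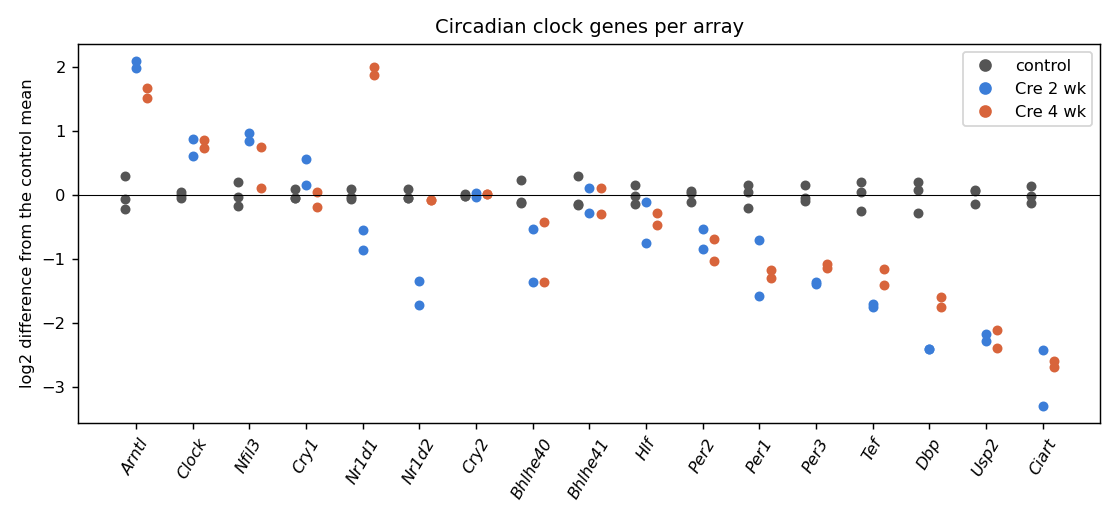
Log2 difference from the control mean (y axis) of the 17 measured circadian clock genes (x axis), with 1 point per array and colours for the control, 2 week and 4 week groups. Arntl, Clock and Nfil3 lie above 0 and Per3, Tef, Dbp, Usp2 and Ciart below 0 on the 4 arrays after Cre, and Nr1d1 lies below 0 at 2 weeks and above 0 at 4 weeks.

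The calls at the 2 times overlapped. Of the genes higher than control, 470 were called at both times, and of those lower, 339, where independent lists of these sizes would share 30 and 19.2 genes. The 3 control arrays could not be split into groups of at least 2, so part of this excess of the counts may come from the shared controls. In 100 simulations of unchanged groups against shared controls the mean overlap was 0.02 and 0, but almost no gene is called there, so this leaves out the effects. With any 1 array left out, the overlap ranged from 22 and 16 (control replicate 3) to 645 and 627 (Cre 2 wk replicate 1), and the second highest was 147 and 107. Fits of 2 groups gave 147 and 82. Across genes, the log2 fold changes at 2 and 4 weeks had a correlation of 0.873, against a mean of 0.401 in the simulations, and genes are not independent replicates. The covariance was 0.0904 against a simulated 0.00573, a difference of 0.0847. The 2 genes called in opposite directions were Nr1d1 and the microRNA gene Mir219a-1, which was at -0.27 at 2 weeks and 0.21 at 4 weeks.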

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

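The tests on clock genes, miR-29 targets and sex-biased genes were chosen after the values they concern had been seen. The count of other splits was planned. The 3 patterns weighed below are hypotheses, since each was found and tested on the same arrays.

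A total of 2171 genes differed between the 4 arrays after Cre and the 3 controls. Of 100 splits of the 7 arrays into groups of 3, 2 and 2 (of 105 possible), 2 gave as many genes, the real one included. A random choice of the 3 control arrays can thus be excluded at the 0.05 level. Splits with the same 3 controls compare the same arrays, so there are fewer distinct groupings than splits. The highest other split gave 2514 genes, and it keeps the same 3 control arrays together and only exchanges arrays between the times. Among splits that part the control arrays, the highest count was 13. These counts cannot separate the loss of Dicer1 from the virus, the weeks or an unrecorded batch that goes with the groups.

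Nr1d1 differed between the times by 2.65 log2 units, and it was singled out because the difference itself passed the test. That call was lost in a fit of these 2 groups alone and when any control array was left out. The control arrays do not enter the difference itself, so these fits change only its estimated spread and degrees of freedom. The p53 target list (-0.32), the acute phase list (-0.43) and the sinusoidal endothelial list (0.21) also differed between 4 and 2 weeks in their mean log2 values, by camera's test of the difference. None of these 3 lists passed with an estimated correlation (adjusted p = 0.17, 0.269 and 0.997 with an estimated correlation). The sinusoidal endothelial difference nearly vanished without Cre 2 wk replicate 1, as given above.

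Probe sets without a single gene name lay outside the comparisons of named genes. Of 3384, 202 changed after Cre by limma (96 higher and 106 lower), a share of 6% against 12.9% of the named genes. The largest changes were those of probe sets 10423049 (3.60, SE 0.41, adjusted p = 0.00897) and 10505266 (-3.08, SE 0.38, adjusted p = 0.0105).

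Of 17 clock genes, 3 rose, 8 fell and 6 did not pass after Cre (camera adjusted p = 0.0159; adjusted p = 0.443 with an estimated correlation), and a different time of day at collection is a candidate explanation. The 4 genes that peak around dawn (Arntl, Clock, Cry1 and Nfil3) and the 13 others differed by 1.88 log2 units in their mean change (0.85 against -1.03, exact permutation over genes, two-sided p = 0.0021; genes are not independent replicates). Such opposed movement is what a shift of phase would give, and the labels used here give no clock time. A change of the clock itself through the loss of Dicer1 stays open as untested: that the clock genes lay farther from the control mean on 4 of 4 arrays after Cre than on each control array only restates the pattern and decides nothing. The 2 explanations cannot be told apart here, because the groups were taken at different weeks and the time of day of each is unknown. Genes such as Nr1d1, Dbp and Thrsp are open to both, and so is any other gene whose level varies over the day.

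The reported miR-29 targets were called higher after Cre as a list, with 4 of 26 rising (camera adjusted p = 0.000674; adjusted p = 0.443 with an estimated correlation). At the preset correlation, a single array as the whole source was ruled out for the average of both times, since the highest adjusted p over the 7 fits that leave out 1 array was 0.00355. More matrix-producing cells may account for part of it, which was weighed by comparing members with the stellate cell markers. The 12 members that are not matrix genes, without Lpl, had a mean log2 fold change of 0.304 against 0.115 for the markers. That difference was 0.19 (permutation p = 0.0397, two-sided, 0.0795 adjusted over 2 tests). The 13 matrix members exceeded the markers by 0.043 (permutation p = 0.402). Neither test decides between more such cells and a rise in hepatocytes, and the stellate cell list itself had a camera adjusted p of 0.168, while the miR-29 list without matrix and stellate genes, Lpl kept, was still called (mean 0.48, adjusted p = 0.00451; adjusted p = 0.538 with an estimated correlation). Release from miR-29 after loss of Dicer1 stays open as the biological explanation, as untested, because mature microRNAs were not measured.

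After Cre, 5 of 18 male-biased genes fell and 2 of 14 female-biased genes rose, and both lists were called by camera (adjusted p = 0.0021 and 0.032; adjusted p = 0.692 and 0.725 with an estimated correlation) and not by fry (0.0541 and 0.154). Female mice among these arrays were ruled out by 3 Y-linked genes (Eif2s3y, Kdm5d and Uty), whose lowest difference from the control mean on an array after Cre was -0.01. Probes shared within the Cyp2 and Cyp3a families remain possible, since the 9 other female-biased genes had a mean of 0.61 (exact sign-flip test over genes, two-sided p = 0.0859). On 2 week replicate 1 the male-biased mean was -0.32, against -0.79 or lower on the other arrays after Cre. The female-biased mean was 0.12 there, near the 0.10 of control replicate 1, against 1.28 to 1.86 on the other arrays after Cre. These values do not show why, and the clock list's mean of -0.75 on 2 week replicate 1 was the lowest of the 4. A loss of sex-biased expression after Dicer1 deletion stays open as a hypothesis.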

How the results depend on the processing

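The fit without tied genes and the lists without single genes or without the matrix and stellate genes were chosen after seeing the data. All other settings were planned. Lpl and Dicer1 kept their direction in every setting run. With 2 to 3 arrays per group the counts depend on the estimate of the spread, and the cause of each shift was not tested unless stated. Counts are given as higher and lower. At 2 weeks (582 and 415) they were 907 and 715 above the 40th percentile of mean level, 913 and 725 above the 60th, 999 and 854 without tied genes, and 171 and 105 in a fit of 2 groups. At 4 weeks (866 and 777) the fit of 2 groups went the other way, to 1001 and 947. With tied genes left out, 1193 genes were lower at 4 weeks and 1 was lower at 4 than at 2 weeks. Between the times, the fit of 2 groups called 0 genes higher. By threshold, the counts at 2 weeks were 96 and 52 with at least 2-fold, 53 and 31 at 0.01, and 1127 and 954 at 0.1. At 4 weeks they were 124 and 98, 108 and 63, and 1428 and 1301. After Cre they were 125 and 84 with 2-fold, 273 and 178 at 0.01, and at 0.1 the lower count was 1583. At 0.01, 0 genes differed between the times. The overlap of the times (470 and 339) was 723 and 599 above the 40th percentile, 753 and 616 above the 60th, 147 and 82 in fits of 2 groups, 812 and 727 without tied genes, and 865 and 744 at 0.1. In fits of 2 groups, Lpl at 2 weeks was at 2.74 (adjusted p = 0.0937) and Dicer1 at -0.76 (adjusted p = 0.0511). Leaving out 1 array in turn gave 24 to 1091 higher and 17 to 1077 lower genes at 2 weeks, 37 to 1001 and 26 to 947 at 4 weeks, 333 to 1426 and 219 to 1362 after Cre, and 0 to 0 between the times in both directions. A group left with 1 array was assumed to vary like the others. Every fit without an array had fewer than 4 residual degrees of freedom, so its counts also reflect lost power. The overlap ranged from 22 to 645 higher and from 16 to 627 lower. Lpl ranged from 1.90 to 3.58 at 2 weeks, 2.32 to 2.63 at 4 weeks and 2.19 to 3.03 after Cre, and Dicer1 from -0.88 to -0.65, -0.71 to -0.62 and -0.77 to -0.66. Without control replicate 1, 2 or 3, Lpl after Cre had an adjusted p of 0.0666, 0.0674 and 0.0759, and without Cre 4 wk replicate 1 or 2 one of 0.0614 and 0.0706. Of values for the other named genes under alternatives, 789 kept direction and call, 183 lost the threshold and 0 reversed. Of list shifts, 268 kept both, 78 lost the threshold, and 1 reversed in its test: the sinusoidal endothelial list between the times without Cre 2 wk replicate 1 (mean 0.012, adjusted p = 0.875), where leaving out 1 array gave 0.012 to 0.405. Of the lost calls of lists, 28 came with the correlation estimated for each list, 14 with fry, 7 above the 40th percentile of mean level and 6 without tied genes. The deposited values carry no background or detection measure, so no limit for dim genes could be set.

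Whether the replicate numbers of the titles pair the arrays is not known. Deviations of equally numbered arrays from their group means correlated at 0.111 between the times and between -0.065 and 0.009 with the controls. In a group of 2 arrays the deviations of replicates 1 and 2 mirror each other, so these few values cannot show that pairing is absent. A fit with the replicate block left 2 fewer residual degrees of freedom and called 0 higher and 0 lower genes at 2 weeks, 1 and 1 at 4 weeks, 0 and 0 between the times, and 2 and 3 after Cre, with an overlap of 0 and 0. With the replicate block Lpl was at 2.72 (adjusted p = 0.136), 2.46 (0.113) and 2.59 (0.0821) in the comparisons at 2 weeks, at 4 weeks and after Cre, and Dicer1 at -0.81 (0.119), -0.71 (0.0912) and -0.76 (0.0683).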

Other observations

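The tests in this part were chosen after the values were seen.

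Of 2 neighbouring imprinted noncoding RNAs, Rian was higher after Cre by 2.69 log2 units (SE 0.56, adjusted p = 0.0339, limma, n = 3 and 4). Meg3 was at 2.61 (SE 0.76) and did not pass (adjusted p = 0.0839). Both varied widely between arrays after Cre: Meg3 read 8.71 and 11.74 at 2 weeks and 9.96 and 11.33 at 4 weeks, against 7.69 to 8.05 in the controls. Rian read 5.55 and 7.60 at 2 weeks and 7.03 and 8.24 at 4 weeks, against 4.12 to 4.75. The protein-coding genes of the same imprinted domain, Dlk1 (0.05, SE 0.09, adjusted p = 0.763) and Rtl1 (0.08, SE 0.05, adjusted p = 0.404), did not pass. These 4 genes were picked after their values were seen.

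The 3 Tnrc6 genes, whose products act with Argonaute proteins downstream of Dicer1, were higher at 4 weeks, while Ago1 and Ago2 were at -0.03 and -0.01. With Dicer1 left out, the microRNA pathway list had a mean of 0.34 after Cre (camera adjusted p = 0.00406, adjusted p = 0.692 with an estimated correlation). Of the p53 targets, the mean without Ccng1, which is also a reported miR-122 target, was 0.53 at 2 weeks (camera adjusted p = 0.000192, adjusted p = 0.272 with an estimated correlation) and 0.23 at 4 weeks (camera adjusted p = 0.361).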
